A study of Mus musculus with 4 samples.

How the data were processed

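The series profiled RNA polymerase I (Pol I) by CUT&Tag in C64 mouse embryonic stem cells. CUT&Tag directs a transposase to chromatin through an antibody, so that sequencing adapters are inserted next to the bound protein. The labels place 4 libraries in 2 groups, with 2 libraries left untreated (control) and 2 from cells given 500 nM auxin for 6 h. Auxin is a plant hormone that is used in animal cells to trigger degradation of proteins carrying an auxin-inducible degron, and the labels used here do not name a degron-tagged protein. They also do not say whether replicates came from separate cultures.

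A single table was analysed here, and it belongs to the whole series. It is a region annotation in 12-column BED layout with no header line, and no column names a library. The BED score column, as deposited by the authors, was 0 in each of the 50727 rows, so it holds no measurement. The remaining numeric columns are positions, exon (block) numbers, block sizes and block starts in bases. Per the submitters' processing notes, the build was mm10 and the tools were FastQC, Bowtie2, deepTools and bedtools. Their versions, parameters and roles, and how the annotation was made, are not given in the sources used here. Read counts, coverage and sequencing depth of the 4 libraries were not analysed here and their depth is unknown, so no interval, detection limit or test between the groups is given. The tests planned between groups were not run for this reason.

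Rows were read with pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15. Gene rows follow the BED convention (start counted from 0), and their positions are printed here counted from 1. For the rDNA rows the block size equalled end minus start plus 1 in 24 of 24 rows, so both printed ends were taken as counted from 1 and included. Rows of the same symbol, contig and strand that shared at least 1 base were merged into a locus, and a gene's span runs from its first to its last base. Loci of different symbols were called overlapping when they shared at least 1 base on either strand. The overlap routine was tested on simulated data with 600 gene names, where 0 pairs differed from an exhaustive comparison. Symbols were looked up in a RefSeq gene table of assembly GRCm38.p6, which gave classes of genes. Of the 26161 gene symbols, 26159 matched as current symbols, 2 as synonyms, and 0 were unmatched. All 24764 symbols with 1 locus, on an assembled chromosome only, that could be compared by position lay inside the span of the same gene in that table. A reference gene was called curated when it had an NM or NR accession. Fisher's exact tests (two-sided) of the 13 lists were run with scipy 1.17.1, and the figure was drawn with matplotlib 3.10.9.

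Before the data were examined, 13 gene lists with 182 distinct symbols were fixed, covering the 3 RNA polymerases and their factors, heat shock factors and chaperones, pluripotency factors, nucleolar genes, histones, non-coding RNA genes and markers of other cell types. The rule for naming genes was also fixed then. It takes every rDNA element, up to 4 members of each list (the first in list order with a row), and the 5 longest and 5 shortest features. Some list symbols without a row are given as well, with their other names, and other genes outside this rule are said to be so. The alternatives tried were merging rows by name, counting identical intervals once, assembled chromosomes only, matching without regard to case, same-strand overlap, overlap of at least 50% of the shorter locus, and exons only. The comparison with curated reference genes, the matching by older and newer names, and the reading of rDNA rows as plain BED were added after seeing the data. The plan treated list content and overlap as descriptive only. The Fisher's exact tests of the lists and the overlap counts by gene class were not part of it.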

Results

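Pol I CUT&Tag was carried out in mouse embryonic stem cells that were either untreated (2 libraries) or exposed to 500 nM auxin for 6 h (2 libraries). The question set by the groups is whether auxin changed Pol I occupancy. Occupancy values for these libraries were not analysed here, so no difference between auxin and control is reported in either direction. The table that was analysed is the genome annotation of the series, which defines the rDNA unit that Pol I transcribes and the genes on the mm10 chromosomes. These are fixed coordinates without replicate error.

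The annotation placed 1 rDNA unit of 45306 bases on a separate contig named R, with 24 element rows on the plus strand. The transcribed part, from the first base of the 5' ETS at position 9307 to the last base of the 3' ETS at position 22709, covered 13403 bases, or 29.6% of the unit. It was divided into 7 elements that met without gaps. The 5' external transcribed spacer (5' ETS, positions 9307 to 13313) held 4007 bases, 18S rRNA (13314 to 15183) held 1870, ITS1 (15184 to 16183) held 1000, and 5.8S rRNA (16184 to 16340) held 157. ITS2 (16341 to 17428) held 1088 bases, 28S rRNA (17429 to 22158) held 4730, and the 3' ETS (22159 to 22709) held 551. The 3 mature rRNAs together made up 6757 bases, or 50.4% of the precursor, and the other 6646 bases were spacer that is removed during rRNA processing.

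Upstream of the precursor the annotation listed 2 promoters separated by a repeat array. The 47S promoter occupied 142 bases (positions 9165 to 9306) and ended at the base before the 5' ETS. The spacer promoter, a second Pol I promoter upstream of the gene promoter, occupied 146 bases (7169 to 7314), and its first base lay 2138 bases upstream of the 5' ETS start. The enhancer repeats between them covered 1746 bases (7391 to 9136). Binding sites for TTF1, the Pol I transcription termination factor, flanked the repeats on both sides. The site named Tsp (7373 to 7390) lay directly upstream of the repeats and 58 bases downstream of the spacer promoter. The site named T0 (9137 to 9154) lay directly downstream of the repeats and 10 bases before the 47S promoter, with its first base at -170 relative to the 5' ETS start.

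**Figure D1:**
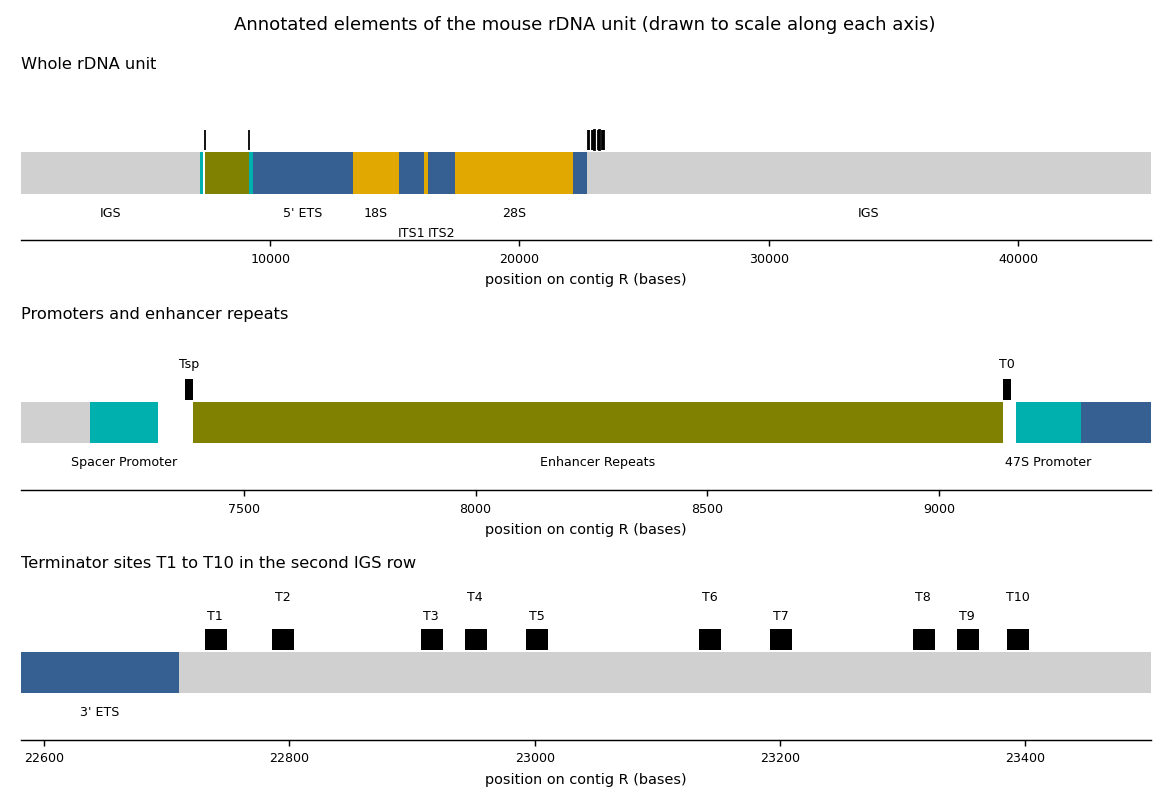
Map of the annotated rDNA elements, with position on contig R in bases on each horizontal axis and no vertical scale. Mature rRNAs are yellow, transcribed spacers blue, promoters turquoise, enhancer repeats olive, intergenic spacer (IGS) grey and TTF1 sites black (widened in the top panel so that they can be seen). The 13403-base precursor takes up 29.6% of the unit, and sites T1 to T10 form an array of 672 bases downstream of the 3' ETS.

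Downstream of the precursor, 10 TTF1 sites named T1 to T10 formed a terminator array of 672 bases, from position 22731 to 23402. T1 began 22 bases after the last base of the 3' ETS. Starts of neighbouring sites were 36 to 141 bases apart, with a median of 55 bases. Each of the 12 TTF1 sites in the unit, Tsp and T0 included, was 18 bases long, and they were the shortest features of the annotation. All 10 terminator sites were nested in the second row of the intergenic spacer (IGS, 22710 to 45306), so signal summed over that row includes the terminators. The IGS was split into 2 rows, the other spanning positions 1 to 7168, and in all it covered 29765 bases, or 65.7% of the unit.

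Outside the rDNA contig the annotation held 50703 transcript rows for 26161 gene symbols. Of these rows, 41836 had a coding part and 8867 had none, and 25623 lay on the plus strand against 25080 on the minus strand. The median row spanned 16610 bases and had 7 exons with a summed exon length of 2344 bases. The 5 longest rows were 3 transcripts of Ptprd (chromosome 4, 75941239 to 78211742, 2270504 bases), Dmd, which encodes dystrophin (chromosome X, 82948870 to 85205050, 2256181 bases), and Cntnap2 (chromosome 6, 45060061 to 47301388, 2241328 bases). The shortest gene row, spanning 28 bases, was that of the small nucleolar RNA gene Snord98 (chromosome 10, 62765579 to 62765606), which is named here after its value was seen. Whether that row covers the whole RNA was not checked. There were 0 rows on a mitochondrial contig.

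The Pol I machinery was covered. Of the 16 symbols in the list of Pol I subunits, 13 had a row. Polr1a, the largest catalytic subunit, spanned 70308 bases on chromosome 6 (71909053 to 71979360) with 34 exons, and Polr1b, the second largest subunit, spanned 25600 bases on chromosome 2 (129100996 to 129126595) with 15 exons. Polr1c on chromosome 17 (4126 bases) and Polr1d on chromosome 5 (34016 bases), which are shared with Pol III, were also present. The 3 symbols without a row, Polr1f, Polr1g and Polr1h, are newer names of genes that the annotation lists as Twistnb, Cd3eap and Znrd1. Of 11 initiation and termination factor symbols, Ptrf had no row, but it is an older name of Cavin1, which had one. The other 10 symbols all had a row. Among them were Ubtf, the upstream binding factor of rDNA (chromosome 11, 102304560 to 102320862, 12 transcripts), Rrn3, which recruits Pol I to its promoter (chromosome 16, 13780699 to 13814841), and the promoter selectivity factor subunits Taf1a (chromosome 1, 21317 bases) and Taf1b (chromosome 12, 59991 bases).

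The general factors and the other polymerases were complete in the lists used. Tbp, the TATA-binding protein shared by the 3 polymerases, spanned 17540 bases on chromosome 17 (15499888 to 15517427) with 1 transcript of 8 exons. All 19 members of the TBP and TFIID list had a row, including Tbpl1, Tbpl2 and Taf1. All 13 symbols of the Pol II list had a row, with Polr2a, the largest subunit, on chromosome 11 (69733997 to 69758633, 29 exons). All 21 Pol III subunits and factors were present, with Polr3a, the largest subunit, on chromosome 14 (24448694 to 24487058, 31 exons).

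The series is titled for heat shock transcription factors, and all 6 symbols of that list had a row. Hsf1, the main activator of the heat shock response, spanned 23794 bases on chromosome 15 (76477362 to 76501155) with 7 transcripts. Hsf2 spanned 26759 bases on chromosome 10 (57486385 to 57513143), Hsf3 150117 bases on chromosome X, and Hsf4 6045 bases on chromosome 8. All 20 heat shock protein and chaperone symbols were present. The stress-inducible Hsp70 genes Hspa1a (chromosome 17, 34969359 to 34972156, 2798 bases) and Hspa1b (34956429 to 34959238, 2810 bases) had a single exon each. Both, and their neighbour Hspa1l, also had a locus on each of 3 alternate contigs of chromosome 17. Of the 26125 symbols on the assembled chromosomes, 1355 (5.19%) had a further locus on another contig. The share in the chaperone list, 3 of 20, was not distinguishable from this. Fisher's exact test (two-sided) gave p = 0.0822, and 1.0 after Benjamini-Hochberg adjustment over 13 lists. The 3 genes are neighbours on the same 3 alternate contigs, so they are not independent, whereas the test counts them as independent.

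All 12 pluripotency factor symbols had a row, among them Pou5f1 (chromosome 17, 4746 bases), Sox2 (chromosome 3, 2467 bases, 1 exon), Nanog (chromosome 6, 7145 bases) and Klf4 (chromosome 4, 5339 bases). Pou5f1, which encodes Oct4, also had loci on 2 alternate contigs. The markers of other cell types were complete, with 10 of 10 fibroblast symbols, such as Col1a1 and Col1a2, and 12 of 12 early differentiation symbols, such as Fgf5 and Otx2. All 16 nucleolar and ribosome biogenesis symbols were present, including Ncl (nucleolin), Npm1 (nucleophosmin), Fbl (fibrillarin) and Nop56. In the histone list, which holds core histones and the linker histones H1f0 and H1f2, 9 of 15 symbols had a row, and the other 6 are older names of genes listed under newer ones, such as H1f2, H2ac4 and H2bc4. These lists concern annotation only and say nothing about expression or occupancy.

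The non-coding RNA list was the least complete, with 7 of 17 symbols. Rmrp, the RNA of RNase MRP (chromosome 4, 43492785 to 43493059, 275 bases), Rpph1, the RNA of RNase P (chromosome 14, 50807447 to 50807771, 325 bases) and Malat1 had rows. So did Lars2, a protein-coding gene (mitochondrial leucyl-tRNA synthetase) that the list includes and that counts among the 7. The symbols Rn45s, Rn18s, Rn28s1 and Rn5s had none, nor did Rn7sk (7SK RNA) or the 7SL RNA genes Rn7s1 and Rn7s2. The symbols n-R5s1, n-R5s100 and Gm26917 had none either. Rn45s, Rn18s, n-R5s1 and Gm26917 are not among the curated reference genes without a row. The low count thus depends in part on which symbols the list holds. Rows named 18S, 5.8S and 28S stood on contig R.

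Signal over a gene is assigned to that gene alone only where its interval is not shared. Of 28072 gene loci on all contigs except R, 6946 (24.7%) shared at least 1 base with a locus of another symbol. Genes with a further locus on another contig were counted there again, and no count over all classes is given for assembled chromosomes alone. By reference class on the assembled chromosomes, 4029 of 20991 protein-coding loci (19.2%) shared a base with another symbol. The share was 74.7% of miRNA loci and 97.6% of snoRNA loci. The 6946 loci formed 4581 pairs, of which 2672 (58.3%) lay on opposite strands and 2686 (58.6%) had one locus entirely inside the other. The count was smaller under each stricter definition, at 4473 loci where at least 50% of the shorter locus was shared, 3951 (14.1%) for exons only and 2447 for the same strand. Among the lists, at least 1 shared base on either strand was seen in 7 of 16 nucleolar genes, 7 of 19 TBP and TFIID genes, 3 of 13 Pol I subunit genes and 0 of 10 fibroblast markers, and these shares were not tested against each other. On the same strand these became 3, 2, 1 and 0 genes, and with 50% of the shorter locus shared 4, 3, 0 and 0. For exons only they were 5, 6, 3 and 0, so the Pol I subunit count did not fall in that setting. The 3 overlapping Pol I subunit genes were Cd3eap (with Ercc1), Polr1e (with Fbxo10) and Polr2k (with Spag1), named here because of their overlap, while Polr1a, Polr1b, Polr1c and Polr1d shared no base with another symbol.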

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

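No paired analysis was possible because the table analysed holds no value per library, and other settings for Pol I occupancy (normalization, low-value filter, pseudocount, precursor against whole rDNA unit, leaving out a replicate) were not run for the same reason. The count of 50727 features depends on what is counted. It became 26184 when rows with the same name were merged, and stayed within 1.5 times when identical intervals were counted once (35680) or only assembled chromosomes were used (47116). The 162 list symbols with a row stayed at 162 without regard to case and on assembled chromosomes alone. They became 169 when older and newer names in the reference table were accepted. Each added symbol is an older name of a gene already counted under its newer name, so no further gene was found. The count of 6946 overlapping loci fell with each stricter definition, to 4473 where 50% of the shorter locus had to be shared, 3951 for exons only and 2447 for the same strand. The 58 curated reference genes without a row became 61 with exact symbols and 92 on assembled chromosomes alone, where fewer rows can match. The summed length of the 7 precursor elements, 13403 bases, became 13396 when each row was read as plain BED, 1 base less per element.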

Other observations

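Small nucleolar RNAs, which guide modification of rRNA in the nucleolus, were almost always annotated inside other genes. Of 123 loci of the reference class snoRNA on the assembled chromosomes, 120 (97.6%) lay inside a locus of another symbol. All 120 of them were on the same strand as a gene around them. The 4 U3 genes without a row, which the reference classes as snRNA, are not among the 123. For miRNA loci the share was 890 of 1227 (72.5%), and 87.2% of those were on the same strand. Only 523 of 20991 protein-coding loci (2.49%) lay inside another locus. Among genes picked after their values were seen, Ncl, Nop56 and Nop58, which encode nucleolar proteins, and Hspa8, a constitutive Hsp70 chaperone, each held 2 snoRNA loci. Also picked after the values were seen, Hspd1 and Hspe1, which encode the mitochondrial chaperonins, shared 96 bases at their divergent 5' ends. Hsf1 shared no base with its neighbour and lay 112 bases from the divergent Bop1, a ribosome biogenesis gene. Signal over the bases that Hspd1 and Hspe1 share cannot be assigned to one of them from the annotation alone.

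The tests in the next 2 paragraphs were chosen after the patterns were seen. Of 26220 curated reference genes, 58 (0.221%) had no row, and 45 of these were rRNA, snRNA, snoRNA, scRNA or Y RNA genes. With rows on the assembled chromosomes alone, 92 genes had no row, the same 45 structural RNA genes among them. The further 34 were 26 protein-coding genes, 7 transcribed pseudogenes and 1 lncRNA gene, so structural RNA genes were then fewer than the others. Classes are those of the reference table, which counts these U3 genes as snRNA although U3 is a small nucleolar RNA. Without a row were 27 of 34 rRNA genes and 11 of 18 snRNA genes, among them 4 U1 and 4 U3 genes and Rn7sk. Both Y RNA genes (Rny1 and Rny3) and 2 of 3 scRNA genes (Rn7s1 and Rn7s2) also had none. By comparison, 10 of 21031 protein-coding genes had no row, 7 of them among the 128 curated genes of the Vmn2r vomeronasal receptor family. Other small RNA classes were nearly or fully covered. In the snoRNA class, which does not hold these U3 genes, 3 of 126 genes (2.38%) lacked a row. None was lacking among guide RNA (0 of 9), RNase P RNA (0 of 4), RNase MRP RNA (0 of 1) and telomerase RNA genes (0 of 1). The lack was thus not general to structural RNA genes. Of the 27 rRNA genes, 26 belong to a single cluster on chromosome 8, so they are not independent, and the difference between classes was not tested because it was noticed in these same genes. In that 5S cluster, with genes of 121 bases, all 26 genes named n-R5s or Rn5s lacked a row while all 6 with Gm names had one. A length minimum is argued against, since 0.182% of the curated genes of 100 bases or less lacked a row. A change of names between annotation releases was looked at as well. Of 55 genes without a row that had a position on an assembled chromosome, 0 had their interval held by a locus of another name (90% of both intervals shared). This test could hardly come out otherwise, so no conclusion is drawn from it. Genes found under a synonym had already been counted as having a row, and 0 symbols of the annotation were left unmatched. Whether these genes were left out because their sequences are repeated in the genome stays open, as no genome sequence was used here, and no biological explanation was tested.

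The rDNA rows follow another coordinate convention than the gene rows. In 24 of 24 rDNA rows the block size exceeded end minus start by 1, whereas in 50703 of 50703 gene rows the last block ended exactly at the row's end. A candidate explanation is that 1-based inclusive coordinates were written into a format that counts starts from 0. With inclusive coordinates, 11 of 13 neighbouring pairs of elements outside the terminator array met with 0 bases between them, as that explanation predicts, and the other 2 pairs were 58 and 10 bases apart. This bears on whether both ends are included, and would be the same with positions counted from 0. The first IGS row starts at 1, which is the first position when counting from 1. With 1-based inclusive coordinates, a program using only the start and end columns as BED would drop the first base of every element. That base is 5.56% of an 18-base TTF1 site and 0.0211% of 28S rRNA. Programs that use the block sizes could treat the rows differently, and none was run. In addition, 23 of the 24 rDNA rows and 0 gene rows ended in a carriage return, which some programs do not accept.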
